A study of Rattus norvegicus with 26 samples.

How the data were processed

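Gene expression was measured with rat Affymetrix arrays in 26 samples of rat tissue and cell lines. The lines descend from BDE1, a line of normal rat bile duct epithelial cells (cholangiocytes). BDEneu cells were transformed with the neu oncogene, the activated rat Erbb2 gene, and BDEsp cells were transformed spontaneously. Either line was inoculated through the bile duct into the livers of male rats of an inbred strain, where it formed tumours. Groups were taken from the sample titles: 6 samples of BDEneu cells, 6 of BDEsp cells, 5 BDEneu tumours, 6 BDEsp tumours and 3 peritoneal metastases of BDEneu tumours. Replicates were numbered in deposit order, so a number names a sample. Title numbers form runs: 3 culture runs each hold 2 BDEneu samples and 1 BDEsp sample, and a further run holds only BDEsp. The labels do not call these runs batches, and permutation tests ignored them except in the test of Erbb2 within culture runs, which was added after the data had been seen. In tumours no run holds both lines, so an effect of runs there could not be removed. The labels do not say whether replicates came from separate cultures or animals, nor whether the metastases came from rats whose tumours were also measured. The p-values therefore measure the spread between these samples, part of which may be technical.

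The deposited values were log2 signals per probe set, made by the authors with RMA per the submitters' processing notes. The RMA version, and which arrays were processed together, are not given in the sources used here. Per the labels, biotinylated cRNA was made from 5 ug of total RNA. The deposited table held 31099 probe sets, with values from 3.03 to 14.95, and sample medians from 6.23 to 6.35. For arrays, the number of samples limits the precision, and no detection calls were used here. The lower quartile of a sample's values lay between 4.87 and 5.05, and a fold against a group at or below it is a ratio of array signals, not of transcripts. Within groups, the lowest correlation between 2 replicates was 0.939, in BDEsp tumours, and no pair of replicates held the same values.

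Probe sets were named through the platform annotation paired with the table. A single gene symbol was given for 20832 probe sets, several symbols for 436 and none for 9831. Of the probe sets with a single symbol, 20764 were matched by gene identifier to the RefSeq gene table of the GRCr8 assembly, which changed no symbol, and 68 kept the platform's symbol. Each gene was represented by the probe set with the highest mean over all 26 samples among those with a single symbol, which gave 14218 genes, of which 4526 had more than 1 probe set. Probe sets with several symbols or none stayed out of the gene-level tests.

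Comparisons were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the genes tested. All adjusted p-values for genes come from these fits. A gene was called at an adjusted p under 0.05 and a difference of at least 2-fold. Cultures were compared in a fit of the 12 culture samples. Tumours and metastases were compared in a fit of the 14 tissue samples. Tumours were compared with cultures, and the culture difference with the tumour difference, in a fit of 23 samples without the metastases. Errors of log2 differences are moderated standard errors (SE) and errors of group means are standard deviations (SD). Values per sample were compared with 2-sided exact permutation tests. The number of genes called in 2 comparisons was set beside the number expected of independent lists.

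The test was first run on simulated data with 200 genes changed among 14218. For the culture comparison it recovered 97% of genes changed by a log2 difference of 1.5 and 100% of those changed by 2.5. For the tumour comparison the shares were 98% and 97%, for metastasis against tumour 95% and 98%, and for the difference of differences 91% and 100%. Between 1 and 5 of 14018 unchanged genes were called. The simulated noise was normal and independent between genes, so these shares need not hold for samples that differ in tissue content.

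The design, the alternatives, the rule for named genes and 32 gene lists were fixed before the data were examined. The lists covered 17 pathways and 15 cell types and named 607 members, of which 542 were matched to a measured gene. Hspa1b was matched to the same gene as Hspa1a, so that list was tested with 17 genes. Each list was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a comparison. Camera with an estimated correlation and fry were run beside it, and fry asks only whether a list's genes move one way on balance. A mean per sample over the measured members served as a marker level. Named genes were the 10 higher and 10 lower called genes with the largest fold and no overlap between groups in the culture and the tumour comparison. In the other comparisons the 5 higher and 5 lower were named, for the difference of differences without the overlap condition. Up to 4 called members per list with the largest fold, Erbb2, and the 5 higher and 5 lower genes with the largest folds in both cultures and tumours were added. Loci without a gene name were passed over.

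Alternatives were every probe set in the fit, the mean of a gene's probe sets, a filter on dim genes (under the 40th percentile), median centring, quantile normalization, eBayes without trend or with robust estimation, sample weights, treat with a 1.5-fold minimum, no fold requirement, an adjusted p under 0.01, 1 fit of all 26 samples, marker means as covariates, runs of consecutive title numbers as a block, and each replicate left out in turn. Fits without samples with unusual marker levels were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.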

Results

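The data were log2 signals of 14218 genes in cultured rat cholangiocyte lines, in the liver tumours these lines formed, and in peritoneal metastases. The 26 samples were 6 of BDEneu cells, 6 of BDEsp cells, 5 BDEneu tumours, 6 BDEsp tumours and 3 BDEneu metastases. The labels call the neu-transformed line BDEneu high grade malignant and the spontaneously transformed line BDEsp low grade malignant. The comparisons asked how the lines differ in culture, how their tumours differ, how metastases differ from tumours, and what sets tumours apart from the cells that formed them.

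The Erbb2 probe set can read both the endogenous and the introduced gene, so its difference between the lines serves as a check of the labels. Erbb2, the rat gene from which the neu oncogene derives, was higher in every BDEneu culture than in any BDEsp culture. Its level was 10.11 ± 0.21 in BDEneu cells and 8.10 ± 0.28 in BDEsp cells (log2, SD, n = 6 each), a 4.03-fold difference (exact permutation p = 0.00216, the smallest 924 splits allow; limma adjusted p = 2.26e-08). Within the 3 runs of title numbers that hold both lines the log2 differences were 1.67, 1.70 and 1.90 (exact permutation p = 0.037, the smallest 27 arrangements allow). In tumours it was 9.38 ± 0.28 (n = 5) in BDEneu and 7.63 ± 0.50 (n = 6) in BDEsp, a 3.37-fold difference (exact permutation p = 0.00433, adjusted p = 0.000295). Metastases had 10.41 ± 0.69 (n = 3), 1.03 above BDEneu tumours on the log2 scale, with every metastasis above every tumour (exact permutation p = 0.0179, the smallest 56 splits allow). The limma adjusted p of 0.0579 did not pass, although it passed in a fit of all 26 samples. That fit also draws on the cultures, where Erbb2 varied less than in metastases and BDEsp tumours. The metastasis mean lay near that of BDEneu cells, and the hepatocyte marker mean was 11.98 in BDEneu tumours and 6.03 in metastases. A rise within the tumour cells therefore cannot be told from a smaller share of liver tissue. The test of whether the difference between lines was another in tumours than in cultures did not pass (log2 difference of differences −0.26 ± 0.27 SE, adjusted p = 0.51).

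**Figure D1:**
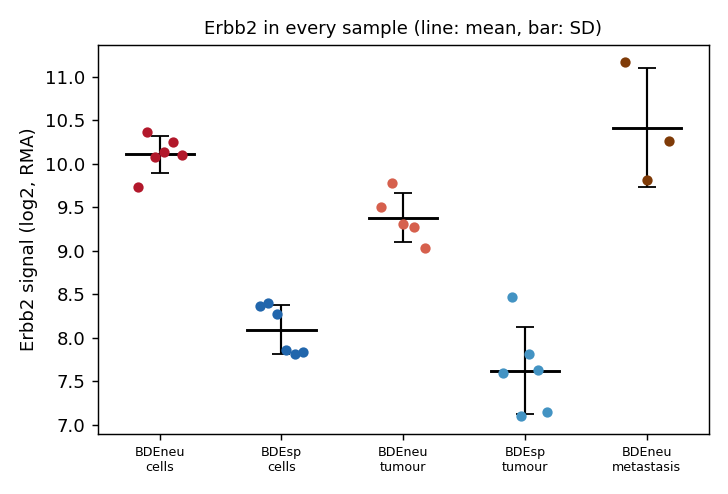
Erbb2 signal (log2, vertical axis) of each sample in the 5 groups, with 1 point per sample, the group mean as a line and the SD as a bar. All 6 BDEneu cultures lie above all 6 BDEsp cultures, and the group means are 10.11 and 8.10.

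In culture, BDEneu cells expressed Ccl2, the monocyte chemoattractant, 99.9-fold above BDEsp cells (log2 difference 6.64 ± 0.45 SE, n = 6 each, adjusted p = 2.66e-08). The tetraspanin Cd81 (6.51 ± 0.27) and the endoderm transcription factor Sox17 (78.8-fold, adjusted p = 5.76e-10) followed. Cdkn2a, which encodes inhibitors of the cell cycle, was 48.3-fold higher (5.59 ± 0.15), and Mtap, an enzyme of methionine salvage, 48.2-fold higher. In the opposite direction, BDEsp cells expressed the calcium-binding protein Ocm 312-fold and the gap junction protein Gja1 250-fold above BDEneu cells (log2 −8.29 ± 0.07 and −7.97 ± 0.08). Of 14218 genes, 788 were higher and 485 lower in BDEneu cells, and 723 and 520 with the runs of title numbers as blocks.

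The other genes of the largest increases were the translation factor gene Eif2s3y of the Y chromosome (6.28), the receptor phosphatase Ptprz1 (5.91), radixin (Rdx, 5.68), Igfbp7 (5.41) and the lactate dehydrogenase subunit Ldhb (5.37). The other genes of the largest decreases were the kinase Rps6ka6 (−6.46), the tight junction claudin Cldn18 (−6.27), Tmem30b (−6.09), the chemokine Ppbp (−6.02), Tspan7 (−5.94), the prostaglandin-degrading enzyme Hpgd (−5.78), the collagen Col3a1 (−5.53) and Marcks (−5.32). Their adjusted p-values were at most 1.35e-10. Over all 14218 genes, the cultures of the lines did not overlap in 3864, where chance gives 0.216% for a gene.

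Among the ERBB receptors and ligands, 3 of 16 measured members rose in BDEneu cells. These were Erbb2, whose probe set can also read the introduced neu gene, the ERBB inhibitor Lrig1 (1.32) and the EGFR ligand Tgfa (1.08). Of 17 genes of ERK pathway output, Dusp6 (1.64) and Dusp5 (1.44) rose and Etv1 (−1.77) fell. Of 23 inflammatory mediators, 6 rose and 2 fell, among them Lcn2 (7.97-fold) and Cxcl3 (log2 2.41) upward and the prostaglandin synthase Ptgs2 (−4.20) downward, with 6 and 2 also adjusted over the list alone. The mesenchymal list was split, with Fn1 (4.69) and the kinase Axl (4.64) higher and Vim (−3.42) lower among 16 members. Among 20 mucin and gastrointestinal genes, Krt20 (4.96) and Muc1 (4.41) rose and Pigr (−4.68) fell. Of 20 hypoxia and glycolysis genes, 3 rose and 3 fell, with Egln3 (3.61) and Car9 (2.86) upward and Slc16a3 (−1.25) and P4ha1 (−1.08) downward. Of 16 oxidative stress genes, 4 rose and 2 fell, led by metallothionein Mt2A (4.36) and Aldh3a1 (−2.11). Of 17 heat shock and immediate early genes, Hspb1 (3.75), Egr1 (2.42) and Fos (1.33) rose and Hsph1 (−1.02) fell. Among 16 p53 targets and CDK inhibitors, Cdkn2a and Cdkn2b (1.85) were higher in BDEneu cells and Zmat3 (−3.33) lower. In BDEsp cells Cdkn2a stood at 4.39, below the lower quartile of the arrays, as did its neighbours Klhl9 (4.07) and Mtap (4.63).

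Of 20 cell division genes, 5 fell, among them Ube2c (−1.45 ± 0.37), Cenpe (−1.33 ± 0.37) and Aurka (−1.31 ± 0.31), with 3 lower adjusted over the list alone. The mean of this list was 7.59 and 7.82 in BDEneu culture replicates 3 and 5 and between 9.40 and 9.85 in the other 4 BDEneu cultures. It was 9.87 ± 0.11 in BDEsp cells (n = 6). Without these 2 cultures none of the 5 calls held and the median of the list was −0.05 in place of −0.83, so these calls rest on them. Each is the first sample of its run of title numbers, as is BDEneu culture 1, whose mean was not low. Without the first sample of each run that holds both lines, 0 members were called and the median was 0.02. The culture comparison as a whole gave 731 higher and 461 lower genes without cultures 3 and 5, with 1042 of the 1273 calls kept. Of 18 DNA replication genes, Ccne2 (−1.43) and Rfc3 (adjusted p = 0.0499) fell, with 1 lower adjusted over the list alone, and neither call held without these 2 cultures. Without them inflammatory mediators counted 3 higher and 4 lower, and Tgfa, Fos, Hsph1 and F11r were no longer called. With the mean of a gene's probe sets Etv1, Smad7, Lss, Ccne2, Rfc3 and Fos were not called.

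Members of the remaining pathway lists were called in small numbers in culture. Of TGF beta response genes, 2 rose and 3 fell, among them Smad7 (1.61), Smad3 (1.36), Itgb6 (−2.13) and Tgfb3 (−1.48). Without BDEneu cultures 3 and 5 these counts were 2 and 5. Other called members were Usp18 (1.70), Bst2 (1.28) and Rsad2 (1.17) among interferon response genes. The sterol genes Insig1 (1.79) and Lss (1.14), the protease Adam8 (2.36) with Plau (−1.40), the junction gene F11r (1.12), and Wnt7a (3.07) with Jag1 (−1.22) were called as well. Of cholangiocyte markers, Sctr (1.90) and Ggt1 (1.37) were higher and Cftr (−1.61) lower. With camera, 0 of the 32 lists passed as a whole in cultures, 3 had an unadjusted p under 0.05, 0 passed with an estimated correlation, and fry passed 15. Camera passed up to 2 lists when a culture was left out, the 2 without BDEneu culture replicate 2.

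In tumours, Ocm was 265-fold lower in BDEneu than in BDEsp (log2 −8.05 ± 0.09 SE, n = 5 and 6, adjusted p = 2.3e-16) and the protease inhibitor Serpinb2 150-fold lower (−7.23 ± 0.19). The mucin Muc13 was 63.5-fold lower (−5.99 ± 0.60) and Agr2, which is needed for mucin folding, 40.5-fold lower (−5.34 ± 0.90). Sox17 was 62.6-fold higher in BDEneu tumours (5.97 ± 0.27) and Cdkn2a 14.6-fold higher (3.86 ± 0.20). In all, 498 genes were higher and 395 lower in BDEneu tumours.

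The other genes of the largest decreases were Lypd8 (−7.21), Ms4a8 (−6.79), the chloride channel regulator Clca4 (−6.71), Palldl1 (−6.42), Cldn18 (−5.84), Gpr15lg (−5.67) and the antimicrobial lectin Reg3g (−5.54). The other genes of the largest increases were Ptprz1 (4.55), the kinase scaffold Akap12 (3.54), Efhd1 (2.98), Mab21l3 (2.85), Tpbg (2.85), the BMP regulator Bmper (2.74), Tp53i11 (2.68) and the ficolin Fcnb (2.68). Their adjusted p-values were at most 0.0067. Over all 14218 genes, the tumours of the lines did not overlap in 3181, where chance gives 0.433% for a gene.

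Of 20 mucin and gastrointestinal genes, 11 fell and 1 rose in BDEneu tumours, also when adjusted over the list alone, with Gcnt3 (−3.63) and Cdh17 (−3.39) beside Muc13 and Agr2. The list's median was −1.60 (camera adjusted p = 6.52e-05, and adjusted p = 0.496 with an estimated correlation). Of 17 cholangiocyte markers, 4 fell, namely Cftr (−3.37), Spp1 (−1.60) and the keratins Krt8 (−1.10) and Krt19 (−1.04). The cholangiocyte list had a camera adjusted p = 0.000352, and an adjusted p = 0.496 with an estimated correlation. Of 18 junction and polarity genes, 3 fell, namely Esrp1 (−1.33), Cldn3 (−1.26) and Dsp (−1.11), with an adjusted p = 0.0219 and an adjusted p = 0.744 with an estimated correlation.

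Lists of fibroblast, endothelial and mesenchymal genes were higher in BDEneu tumours. Of 23 fibroblast and myofibroblast genes, 13 rose, with Fbln1 (2.35 ± 0.24), the collagens Col1a1 (1.82 ± 0.28) and Col5a1 (1.74 ± 0.37) and the collagen crosslinking enzyme Lox (1.81 ± 0.33). The list's median was 1.17 (adjusted p = 9.28e-08, and adjusted p = 0.548 with an estimated correlation). Of 18 endothelial genes, 12 rose, led by Sox17 (5.97), which is a member of this list. Nos3 (2.13 ± 0.19), Emcn (1.98 ± 0.46) and Lyve1 (1.76 ± 0.49) followed. The median of the endothelial list was 1.31 (adjusted p = 9.28e-08, and adjusted p = 0.496 with an estimated correlation). Of 16 mesenchymal genes, Tnc (2.10), Axl (1.99), Zeb2 (1.30) and Itga5 (1.04) rose (adjusted p = 0.000492, and adjusted p = 0.496 with an estimated correlation). Counts adjusted over the list alone were 13, 12 and 5 in these 3 lists. Some of these genes were already higher in BDEneu cells in culture: Fbln1 (2.56), Col5a1 (1.41), Esam (1.33), Sox17 and Axl (4.64). Col5a1 was not called in culture with the mean of a gene's probe sets. Fbln1 and Axl were no higher in BDEneu tumours (8.66 and 10.08) than in BDEneu cells (8.97 and 11.39). Among members not called between cultures, 11 of 20 fibroblast, 10 of 16 endothelial and 3 of 13 mesenchymal genes rose in tumours, with medians of 1.13, 1.31 and 0.66. The means of the endothelial and mesenchymal lists were also higher in BDEneu cultures, by 0.47 and 0.45 (exact permutation p = 0.00216 each). Their median log2 differences in culture were −0.013 and 0.01, with 2 members called higher in each list, so a few genes set these means. With the fibroblast marker mean as a covariate, 2 endothelial genes were called in place of 12, and the comparison gave 319 higher and 430 lower genes. That mean did not overlap between BDEneu tumours (11.1 to 11.6) and BDEsp tumours (9.8 to 10.3). As a covariate it thus takes up part of any difference between them, so the lost calls cannot show that both lists move together.

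Some T cell and NK cell genes went the other way. Of 22 T cell and NK cell genes, 6 fell in BDEneu tumours, with 7 adjusted over the list alone. Cd8a, the co-receptor of cytotoxic T cells, was 9.97-fold lower (−3.32 ± 0.24), and the granule proteins Gzma (−3.15 ± 0.49), Gzmb (−3.01 ± 0.42) and Prf1 (−1.76 ± 0.36) fell with it. The list's median was −0.24, with a camera adjusted p = 0.021, and an adjusted p = 0.744 with an estimated correlation. It did not pass with dim genes left out (adjusted p = 0.765), its adjusted p ranged from 0.00977 to 0.0627 with a replicate left out, and its member Cd4 had a log2 difference of 0.57. The mean of the list was 6.22 ± 0.09 in BDEneu tumours (n = 5) and between 6.57 and 7.86 in BDEsp tumours (n = 6; exact permutation p = 0.00433), with BDEsp tumour replicate 1 at 7.86. The B cell gene Pou2af1 (−2.19) also fell. In the lists of mast cells, mesothelial cells, adipocytes, muscle, pancreatic acinar cells and erythroid cells, at most 2 members were called in tumours. Of 7 neutrophil genes, 3 rose, among them S100a8 (2.11) and Csf3r (1.41), with an adjusted p = 0.0105, an adjusted p = 0.496 with an estimated correlation, and an adjusted p = 0.101 with dim genes left out. Among 21 macrophage and dendritic cell genes, Csf1r (1.47) and Lyz2 (1.29) rose and Cd163 (−2.35) and Cd14 (−1.62) fell.

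Other pathway lists had members called both ways in tumours. Of 23 inflammatory mediators, 5 rose and 2 fell, with Csf3 (2.04), Cxcl1 (1.89) and Lcn2 (1.75) upward and Ccl20 (−1.90) downward. Of 19 matrix proteases and inhibitors, 5 rose and 3 fell, with Adamts1 (1.98) and Mmp19 (1.57) upward and Mmp7 (−2.44) and Mmp13 (−1.68) downward. Of 16 TGF beta response genes, Smad7 (1.82), Tgfb1 (1.58) and Ccn1 (1.29) rose and Itgb6 (−1.85) fell. Among ERBB receptors and ligands, Egfr (1.28) rose with Erbb2 and Lrig1 (−1.20) fell. Among ERK output genes, Dusp5 (1.06) rose and Etv1 (−1.94) and Spry1 (−1.67) fell. Of the oxidative stress genes, Mt2A (1.95) rose and Slc7a11 (−2.54), Aldh3a1 (−1.95) and Akr7a3 (−1.50) fell. The hypoxia genes Car9 (−1.71) and Ndrg1 (−1.44) fell. The lipid genes Scd (2.81), Fasn (1.18) and Acly (1.10) rose (list adjusted p = 0.0426, and adjusted p = 0.744 with an estimated correlation), and this list did not pass without BDEneu tumour 5 and BDEsp tumour 4 (adjusted p = 0.177).

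Liver tissue differed between the tumour samples themselves. The hepatocyte marker mean was 11.98 ± 0.62 in BDEneu tumours (n = 5) and between 5.71 and 12.65 in BDEsp tumours (n = 6; exact permutation p = 0.16). In BDEsp tumour replicate 4 it was 5.71, near the 5.44 ± 0.12 of cultured BDEsp cells (n = 6). The list of 25 hepatocyte genes had a median of 1.79 (adjusted p = 0.0169, and adjusted p = 0.744 with an estimated correlation), although limma called 0 of its members, with 2 higher and 1 lower at an unadjusted p under 0.05. In the fit of all 26 samples, which also draws on the less variable cultures, 8 were higher. Without BDEneu tumour 5 and BDEsp tumour 4 the list did not pass (median 0.70, adjusted p = 0.113), nor did it with dim genes left out (adjusted p = 0.0827). The pancreatic acinar mean was 8.75 in BDEneu tumour replicate 5 and 6.52 in replicate 2, and at most 5.94 in the other tumours. Without BDEneu tumour 5 and BDEsp tumour 4, 449 genes were higher and 355 lower, of which 759 calls were shared with the 893. Among the members named above, Dsp, Krt19, Lyve1, Fasn, Acly and Mmp13 were not called without them, and Egfr, Zeb2 and Dsp were not called with the mean of a gene's probe sets.

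**Figure D2:**
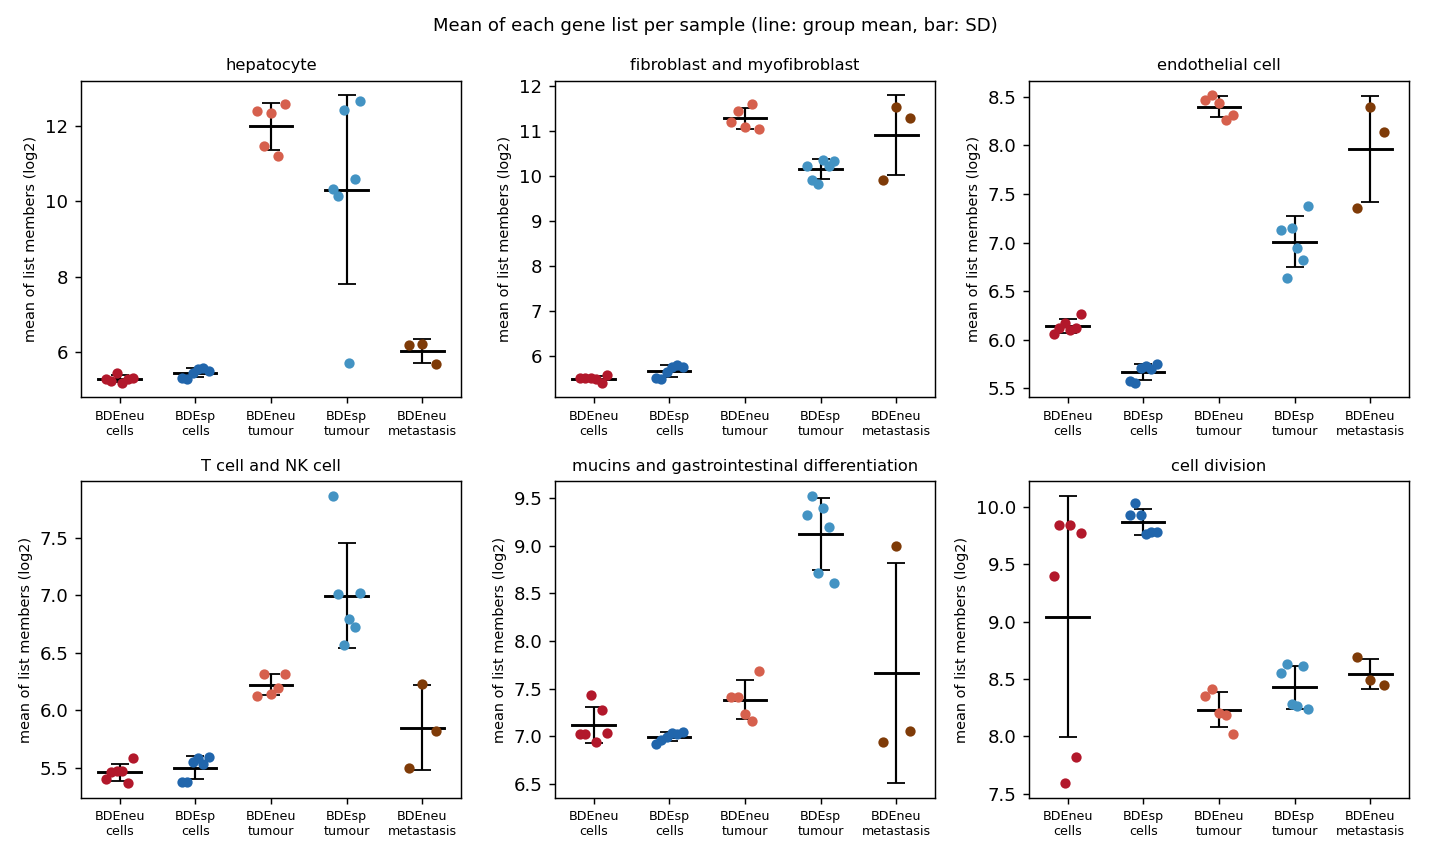
Mean log2 signal (vertical axes) of the members of 6 gene lists in each sample of the 5 groups, with 1 point per sample, the group mean as a line and the SD as a bar. Fibroblast and endothelial means are higher in BDEneu than in BDEsp tumours, T cell and NK cell and mucin means are lower, and the hepatocyte mean of 1 BDEsp tumour lies at 5.71.

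The difference between the lines in culture was partly found in their tumours. Of the called genes, 187 were higher in BDEneu in both cultures and tumours, where 27.6 would be expected of independent lists, and 125 were lower in both, where 13.5 would be expected. Another 18 genes were higher in cultures and lower in tumours, and 10 the reverse. The comparisons share no sample. The genes with the largest differences in both were Sox17, Ptprz1, Cdkn2a, Akap12 (5.08 in cultures and 3.54 in tumours) and Tpbg (4.12 and 2.85) upward. Downward they were Ocm, Cldn18, Ppbp (−6.02 and −5.35), Slc6a14 (−5.05 and −5.26) and Tmem30b (−6.09 and −4.48). Across genes, which are not independent replicates, the log2 differences had a Pearson r of 0.423 and a Spearman rho of 0.395.

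**Figure D3:**
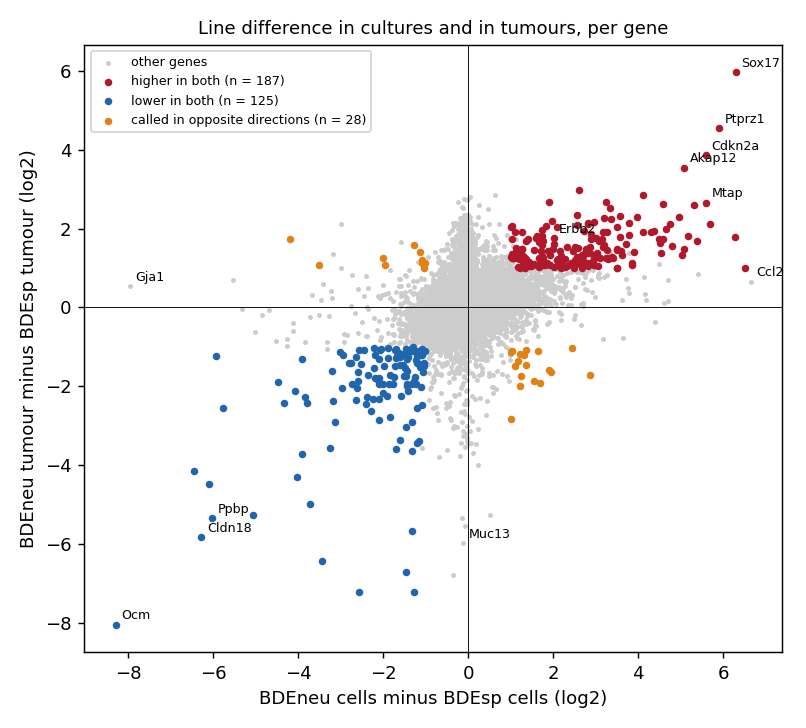
Log2 difference between BDEneu and BDEsp for each of 14218 genes, in cultures on the horizontal axis and in tumours on the vertical axis. Red points are the 187 genes higher in both, blue points the 125 lower in both and orange points the 28 called in opposite directions; grey points are all other genes.

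Peritoneal metastases of BDEneu tumours had lower levels of liver genes than the tumours at the primary site. The drug-metabolizing enzymes Cyp2c6v1 and Cyp3a2 were 242-fold and 199-fold lower in metastases (log2 −7.92 ± 1.49 SE and −7.63 ± 1.32, n = 3 and 5, adjusted p = 0.0166 for both). The plasma proteins Serpinc1 (−7.57), Ahsg (−7.55) and Itih4 (−7.54) followed. Of 25 hepatocyte genes, 23 fell, with 25 adjusted over the list alone and a median of −6.26. In all, 331 genes were lower and 85 higher in metastases. The genes of the largest increases were the peptidase Cndp1 (2.83 ± 0.44), the keratin Krt12 (2.23 ± 0.31), the epithelial transcription factor Tfcp2l1 (2.06 ± 0.50), Clic5 (1.97 ± 0.42) and Pex11a (1.77 ± 0.42).

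Single members of other lists fell too: Scd (−6.23) of fatty acid synthesis, Pck1 (−5.38) of the adipocyte list, Pigr (−4.64) of the mucin list and Gstm1 (−3.77) of oxidative stress. The liver macrophage receptor Clec4f (−2.31) and the sinusoidal endothelial gene Stab2 (−1.22) fell as well. Each list member named here lost its call with at least 1 replicate left out. The neutrophil genes S100a8 (1.51), S100a9 (1.39) and Mmp8 (1.34) rose, as did the EGFR ligand Btc (1.37), while Egfr (−1.29) fell. Fosl1 (1.29) and Dusp5 (1.05) rose among ERK output genes, whose list had a median of 0.56 (camera adjusted p = 0.000356, and adjusted p = 0.501 with an estimated correlation). Lists of cell division, DNA replication, junctions and hypoxia had medians of 0.33, 0.38, 0.64 and 0.43 (adjusted p from 6.98e-05 to 0.000506, and adjusted p = 0.501 with an estimated correlation for each). With the hepatocyte mean as a covariate these medians were 0.33, 0.32, 0.035 and 0.27, that of ERK output 0.09 and that of the interferon list −1.13. The hepatocyte mean was 5.67 to 6.22 in metastases and 11.19 to 12.56 in BDEneu tumours. As it separates these groups, the fit cannot decide which of these shifts come from liver content. Lists of fibroblasts, stellate cells, endothelial cells, macrophages and T cells had medians of −0.31, −0.25, −0.44, −0.32 and −0.34 (camera adjusted p = 0.00522, 0.00469, 0.00138, 0.00126 and 0.00112, and adjusted p = 0.595, 0.501, 0.501, 0.501 and 0.501 with an estimated correlation). Without metastasis replicate 1 the fibroblast, endothelial and macrophage lists did not pass (adjusted p = 0.603, 0.247 and 0.137). With dim genes left out the stellate, endothelial and T cell lists did not pass (0.159, 0.0709 and 0.107). No member of the cell division list was called by limma, with 9 higher at an unadjusted p under 0.05. The interferon list had a median of −0.64, with Ifit2 (−1.26) and Ifi27 (−1.07) lower (adjusted p = 1.11e-05, and adjusted p = 0.501 with an estimated correlation). Camera passed 14 lists in all, fry passed 1, and camera with an estimated correlation 0, with 1 at an unadjusted p under 0.05.

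The pancreatic acinar mean was 10.96 in metastasis replicate 2, against 5.31 and 5.16 in the other metastases. The hepatocyte mean was 6.03 ± 0.31 in metastases (n = 3) and 11.98 ± 0.62 in BDEneu tumours (n = 5; exact permutation p = 0.0179, the smallest 56 splits allow). With this mean as a covariate limma called 2 genes higher and 1 lower, at an adjusted p under 0.01 it called 0 higher and 4 lower, and treat called 2 and 81. Because the hepatocyte mean does not overlap between the groups, few calls with it as a covariate follow from its construction. Without metastasis 2 and tumour 5, which hold pancreatic markers, 166 genes were higher and 267 lower, and Clec4f, Stab2, S100a8, S100a9, Egfr and Ifit2 were no longer called while 23 hepatocyte genes were lower. Counts also moved with single samples: 1 higher and 3 lower without metastasis 1, 219 higher without metastasis 2 and 92 lower without metastasis 3, and 29 and 142, 20 and 114, and 38 and 147 without tumours 1, 3 and 5.

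Compared with the cells that formed them, BDEneu tumours held genes of many cell types that cultures did not. Albumin (Alb) stood at 14.73 ± 0.25 in tumours, near the highest signal of the arrays, and at 5.06 ± 0.24 in cells (log2, SD, n = 5 and 6). The plasma selenoprotein Selenop was 802-fold higher, Fgg 721-fold, Col1a1 609-fold and the matrix protein Postn 604-fold. BDEsp tumours likewise exceeded BDEsp cells in Selenop (514-fold), Postn (311-fold), the matrix protein Mgp (308-fold), the fatty acid carrier Fabp4 (281-fold) and the class II gene RT1-Da (244-fold; n = 6 each). Counts were 1643 higher and 1038 lower for BDEneu, and 1569 higher and 819 lower for BDEsp. Both tumours were higher than their cells in 1138 of these genes, where 181.3 would be expected of independent lists, and lower in 417, where 59.8 would be expected.

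Of 23 fibroblast genes, 22 rose in either tumour, with medians of 5.94 in BDEneu and 4.65 in BDEsp, and all 21 macrophage and dendritic cell genes rose, with medians of 5.34 and 4.99. Endothelial genes (13 and 10 of 18) and mesenchymal genes (11 and 9 of 16, with 1 lower in BDEneu) rose as well. These 4 lists passed camera also with an estimated correlation, with adjusted p between 0.00202 and 0.0344. All 25 hepatocyte genes rose, with adjusted p = 0.219 and 0.23 with an estimated correlation. T cell and NK cell genes rose in 7 of 22 members in BDEneu and 15 of 22 in BDEsp tumours, with adjusted p = 0.28 and 0.136 with an estimated correlation. Of 20 mucin and gastrointestinal genes, 13 rose and 1 fell in BDEsp tumours, such as Agr2 (6.37) and Muc13 (5.47), with an adjusted p = 2.05e-07 and an adjusted p = 0.0645 with an estimated correlation, while 3 rose and 4 fell in BDEneu tumours. Of 23 interferon and antigen presentation genes, 14 and 16 rose, with adjusted p = 0.165 and 0.0595 with an estimated correlation.

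In BDEneu tumours, the largest decreases against cells were in Zfp185 (−3.90 ± 0.11), Scel (−3.65 ± 0.46), Vsnl1 (−3.46), Akr1b8 (−3.33) and Mbnl3 (−3.33). In BDEsp tumours they were in the cytokines Csf3 (−3.59 ± 0.18), Cxcl1 (−3.55 ± 0.26) and Il24 (−3.10), the glutamate transporter Slc1a1 (−2.97) and the transcription factor Fosl1 (−2.88). The EGFR ligands Areg (−2.42 in both) and Hbegf (−1.78 and −1.53) fell in either tumour. Of 20 cell division genes, 18 fell in BDEsp tumours, with a median of −1.50 (adjusted p = 0.0004, and adjusted p = 0.51 with an estimated correlation), and 5 fell in BDEneu tumours, where the list did not pass (adjusted p = 0.0919). Of 18 DNA replication genes, 16 fell in BDEsp and 8 in BDEneu tumours, with adjusted p = 0.51 and 0.646 with an estimated correlation. Without BDEneu cultures 3 and 5, whose cell division means were low, and BDEneu tumour 5, 19 cell division and 17 DNA replication genes fell. Mdm2 (−1.92 and −1.79) and Plk2 (−1.81 and −2.29) led the p53 targets, of which 7 and 6 of 16 fell and 1 rose in BDEneu, with adjusted p = 0.131 and 0.0544 with an estimated correlation. Camera passed 21 and 22 lists, fry 27 and 27, and camera with an estimated correlation 4 and 4. The median of all genes lay at −0.15 for BDEneu and −0.10 for BDEsp, so small decreases are to be read relative to that. Tumour samples also held other tissue, with a hepatocyte mean of 11.98 in BDEneu tumours and 5.29 in BDEneu cells. A decrease within the tumour cells therefore cannot be told from a smaller share of these cells in the sample. Without the fold requirement 6066 and 5316 genes were lower.

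The difference between the lines was itself different in tumours and cultures for 1299 genes. Gja1 was 7.97 lower on the log2 scale in BDEneu cells than in BDEsp cells but 11.51 ± 0.26 and 10.97 ± 0.41 in their tumours (SD, n = 5 and 6), a difference of differences of 8.51 ± 0.20 SE. Col3a1 (6.22), Ptgs2 (5.93), Marcks (5.28) and Rgn (5.09) followed. In the other direction, Ms4a8 (−6.42), Ccl2 (−5.99), Lypd8 (−5.92), Muc13 (−5.87) and Ly6al (−5.79) had a far lower BDEneu to BDEsp difference in tumours than in cultures. In all, 582 genes had a positive and 717 a negative difference of differences. Col3a1 is a member of the fibroblast list and Rgn of the hepatocyte list, and tumours hold tissue that cultures lack. A change within the lines therefore cannot be told from signal of other cells in the tumours.

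Of the 20 mucin genes, 13 had a negative difference of differences and 1 a positive one, among them Agr2 (−5.19) and Muc1 (−4.77), with Pigr (4.62) opposite. With 14 negative adjusted over the list alone, the list's median was −1.99 (adjusted p = 2.42e-08, and adjusted p = 0.099 with an estimated correlation). Muc13 stood at 4.87 ± 0.15 in BDEneu cells and 4.99 ± 0.12 in BDEsp cells (n = 6 each), and at 4.47 ± 0.07 (n = 5) and 10.46 ± 0.88 (n = 6) in their tumours. Cholangiocyte markers were negative in 6 of 17, among them Ggt1 (−2.22) and Epcam (−1.64), and oxidative stress genes in 7 of 16, led by Akr7a3 (−2.59), each with an adjusted p = 0.099 with an estimated correlation. Fibroblast genes were positive in 14 of 23, such as Lox (2.10) and Col1a1 (1.83), and endothelial genes in 9 of 18, such as Emcn (2.03) and Pecam1 (1.76), again with an adjusted p = 0.099 with an estimated correlation. Of 22 T cell and NK cell genes, 7 were negative, led by Cd8a (−3.30) and Gzma (−3.18), with adjusted p = 0.0255, an adjusted p = 0.7 with an estimated correlation, and an adjusted p = 0.246 with dim genes left out. The hypoxia genes Car9 (−4.57) and Egln3 (−3.42) were among 5 of 20 negative members, and that list did not pass (adjusted p = 0.0527).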

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

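The T cell and NK cell test below was chosen after its result had been seen, the division of fibroblast and endothelial genes by culture was added late, and the fits without samples with unusual markers were added after the data had been seen. Chance alone sets a sample apart in about 1 in 20 groups, and 9 of the 132 groups tested held such a sample.

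The hepatocyte mean was 5.71 in BDEsp tumour replicate 4 and 10.15 to 12.65 in the other BDEsp tumours. The T cell and NK cell mean was 7.86 in BDEsp tumour replicate 1, against 6.57 to 7.02 in the others. BDEsp tumour replicate 6 stood above its group in the mesenchymal mean (8.42, others 8.11 to 8.21) and the mesothelial mean (6.06, others 5.61 to 5.73). BDEsp tumour replicate 3 had a Wnt, Notch and Hedgehog mean of 6.22, with the others at 6.34 to 6.40. BDEneu tumour replicate 3 had a junction mean of 8.98 (others 9.24 to 9.28), and replicate 2 a cholangiocyte mean of 9.78 (others 9.56 to 9.61). In cultures, BDEsp cells replicate 2 had a sterol and fatty acid mean of 10.02 (others 9.76 to 9.83), and BDEneu cells replicate 1 an oxidative stress mean of 8.71 (others 8.88 to 8.94).

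The difference between BDEneu and BDEsp was not the same in tumours as in cultures, by the test of the difference of differences. Signal of other cells in the tumour samples was not separated from a change within the lines. The difference was higher in tumours for 582 genes and lower for 717, and 1 of 100 splits of the samples, the real one, gave as many as its 1299 genes, where the highest other gave 503. Single genes with the largest positive values were Gja1 (8.51), Col3a1 (6.22), Ptgs2 (5.93), Marcks (5.28) and Rgn (5.09), and with the largest negative values Ms4a8 (−6.42), Ccl2 (−5.99), Lypd8 (−5.92), Muc13 (−5.87) and Ly6al (−5.79). Lists past camera at the preset correlation had medians of −1.99 (mucins), −0.75 (oxidative stress), −0.57 (cholangiocyte), −0.56 (junctions), −0.20 (T cell and NK cell), 0.41 (TGF beta), 0.64 (macrophage), 0.94 (endothelial), 1.25 (fibroblast) and 1.89 (hepatocyte). None of these 10 lists passed camera with an estimated correlation, where 5 lists had an unadjusted p under 0.05, and fry passed 16 lists.

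Fibroblast and endothelial markers were higher in BDEneu tumours, with a median log2 difference of 1.18 over 41 members, of which Fbln1, Col5a1, Esam and Sox17 were higher in BDEneu cultures already, so the cells themselves may account for these 4, while 21 of the 36 not called in culture rose. The T cell and NK cell mean was lower in BDEneu tumours (exact permutation p = 0.00433). Lymphocytes may differ on their own, so this cannot decide whether BDEneu tumours held a lower share of tumour cells. The cholangiocyte mean was lower in BDEneu tumours (−0.67, exact permutation p = 0.00216) but higher in BDEneu cultures (0.14). In tumours the neutrophil mean was higher (0.995) and the B cell mean lower (−0.275, exact permutation p = 0.00216 each). More liver tissue in these samples is argued against, since the median of the 41 members was 1.26 with the hepatocyte mean as a covariate. For the others, a lower share of tumour cells stays open. So does a difference in how the tumours of these 2 lines of different grade recruit stroma and vessels, and either may be the source. With the fibroblast mean as a covariate 2 of 18 endothelial genes were called in place of 12, with a median of 0.43 in place of 1.31, while over all genes 319 were higher. The fibroblast mean did not overlap between these groups, so this loss follows in part from the construction of the covariate and decides nothing.

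The genes lower in metastases may reflect liver tissue within the primary tumour samples. Outside the hepatocyte list there were 308 of them, and their median correlation with the hepatocyte mean across the 6 BDEsp tumours, which are not part of this contrast, was 0.88 (0.979 without the 2 tumours farthest from the median, −0.158 for genes not called). A difference in the tumour cells themselves was not tested apart from this and stays open. Of the 85 genes higher in metastases, 83 (97.7%) kept a log2 difference of at least 1 without metastasis replicate 2 and BDEneu tumour 5. The size of these differences thus does not rest on the pancreatic tissue in those samples. The choice of called genes largely fixed this result, since genes raised in 1 metastasis only vary too much to be called. Even of the pancreatic acinar genes, 0 were higher at an unadjusted p under 0.05.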

How the results depend on the processing

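Fits without samples with unusual marker levels, or without the first sample of each culture run of title numbers, were added after the data had been seen, and the other alternatives were planned. Tumours without the BDEsp samples with title numbers 28 and 30 gave 505 and 372. Of the values that answer a comparison, 441 stayed on the same side or within 1.5 times, 64 moved by more and 2 passed where they had not. No difference of a gene named by fold changed sign, but the balance of counts turned: tumours had more lower than higher genes with no fold requirement, treat, the fibroblast covariate and quantile normalization (434 and 437), metastases more higher genes with no fold requirement and the hepatocyte covariate, tumours against cells more lower genes with no fold requirement, and the difference of differences more higher genes with sample weights (830 and 707). Of the alternatives for genes named by fold, 335 were the same, and the 9 that lost their call did so in metastasis against tumour with single replicates left out. Of the named list members, 62, 73, 23, 110, 109 and 78 in the order of comparisons below, 8, 7, 1, 2, 5 and 5 lost their call with the mean of probe sets, 11, 12, 9, 5, 0 and 7 without the samples with unusual markers, 1, 0, 0, 1, 0 and 0 in the fit of all 26 samples, and 7, 14, 23, 6, 4 and 4 with at least 1 replicate left out. Erbb2 has a single probe set, so its other probe sets were not run, and sample weights did not fully converge in 2 fits. Median centring and quantile normalization moved no count by more than 1.5 times. No detection calls were used, so the floor of dim genes was not separated from background.

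With every probe set tested, which adds tests, counts (higher and lower) were 1332 and 774 for cultures, 856 and 604 for tumours, 194 higher for metastases, 2549 and 2108 for BDEneu tumours against cells, 1525 lower for BDEsp tumours against cells, 1023 and 1190 for the difference of differences, and 291 and 197 shared by cultures and tumours. With no fold requirement, which admits smaller changes, they were 2976 and 2855 for cultures, 2383 and 2708 for tumours, 743 and 484 for metastases, 3357 and 6066 for BDEneu and 3396 and 5316 for BDEsp tumours against cells, 1943 and 2208 for the difference of differences, and 1146 and 1168 shared. With dim genes left out, so that fewer were tested, they were 313 and 257 for tumours, 953 higher for BDEneu and 985 higher for BDEsp tumours against cells, 366 higher for the difference of differences and 83 lower in both cultures and tumours. With treat, a stricter test, they were 190 and 230 for tumours, 2 and 81 for metastases, and 331 and 470 for the difference of differences.

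For metastases, an adjusted p under 0.01 gave 0 higher and 4 lower in limma (85 and 331 at 0.05), the hepatocyte covariate 2 and 1, sample quality weights 509 lower, the fit of all 26 samples 497 lower, and the fit without metastasis 2 and tumour 5 gave 166 higher. The fibroblast covariate gave 319 higher for tumours. Erbb2 in metastases passed in the fit of all 26 samples (1.03), which also draws on the less variable cultures, and with some replicates left out. Over all fits with a replicate left out its smallest difference was 0.66, below the 2-fold minimum. Its signal was 11.16 in metastasis 1, against 9.82 and 10.26 in the other metastases. Lists past the threshold numbered 15, 1 and 16 with fry for cultures, metastases and the difference of differences. With an estimated correlation camera passed 0, 0 and 0 for tumours, metastases and the difference of differences (2, 1 and 5 at an unadjusted p under 0.05), and 4 and 4 for BDEneu and BDEsp tumours against cells. Apart from the construction of each alternative, the cause was not tested.

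With each replicate left out in turn, higher and lower counts ranged over 738 to 833 and 433 to 509 for cultures, 435 to 627 and 358 to 435 for tumours, and 1 to 219 and 3 to 475 for metastases. They ranged over 1625 to 1672 and 964 to 1125 for BDEneu tumours against cells, 1512 to 1643 and 745 to 884 for BDEsp, 562 to 721 and 687 to 770 for the difference of differences, and 171 to 203 and 117 to 130 for genes shared by cultures and tumours. Lists ranged over 0 to 2 for cultures, 8 to 13 for tumours, 13 to 17 for metastases, 18 to 21 and 19 to 23 for tumours against cells, and 9 to 12 for the difference of differences.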

Other observations

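The genes named here for their position and the tests of neighbouring genes and of chromosomes in cultures were chosen after their values or the pattern had been seen, while the chromosome 18 tests in tumours and without 2 cultures, and the splits, were set beforehand. On rat chromosome 5, the neighbouring genes Klhl9, Mtap, Cdkn2a and Cdkn2b (order from GRCr8) had signals of 4.07, 4.63, 4.39 and 5.80 in BDEsp cells and 9.08, 10.22, 9.98 and 7.65 in BDEneu cells (n = 6 each). Of genes farther out with signals well above the floor, Focad differed by −0.27, Caap1 by −0.45 and Plaa by −0.83 on the log2 scale, and Dmrta1 and Elavl2, at 4.01 to 4.61 in either line, were too dim to be read. In tumours the differences were 1.32 for Klhl9, 2.66 for Mtap, 3.86 for Cdkn2a and 0.54 for Cdkn2b. Around Sox17, the neighbours Atp6v1h (2.89), Tcea1 (1.67), Lypla1 (1.82) and Mrpl15 (2.81) were also higher in BDEneu cells. Farther out, Tmem68 (−0.66), Tgs1 (−0.73), Oprk1 (−0.35) and Lyn (−0.35) were lower, and the dim genes Rp1 (−0.02) and Xkr4 (−0.05) did not differ. Of Y chromosome genes, Eif2s3y stood at 9.54 ± 0.24 in BDEneu and 3.26 ± 0.10 in BDEsp cells (SD, n = 6 each), whereas Uty stood at 8.69 ± 0.57 and 8.77 ± 0.17.

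Called genes lay beside each other in genome order more often than in random orders of the same genes, over 7648 genes with a signal at or above the median in at least 1 line. Among genes higher in BDEneu cells there were 158 neighbouring pairs, where 10000 random orders gave 56.5 on average and 83 at most (permutation p = 1e-04, the smallest they can give). Among genes lower there were 66, where random orders gave 19.4 on average and 38 at most (permutation p = 1e-04, again the smallest). For tumours there were 20 and 14 pairs, against means of 6.49 and 7.66 (permutation p = 1e-04 and 0.025). By chromosome, the mean log2 difference between BDEneu and BDEsp cells of the genes at or above the median signal, relative to all such genes, was 0.42 on chromosome 4, 0.35 on 6, −0.26 on 5, −0.29 on 12, −0.37 on 15, −0.36 on 16 and −0.40 on 17, and smaller on the rest apart from chromosome 18. In tumours the shift was 0.03 on chromosome 4 (exact permutation p = 0.561), 0.12 on 6, −0.06 on 5, −0.24 on 12, −0.10 on 15, −0.17 on 16 and −0.15 on 17, and the last 6 passed the same test. Chromosome 20 went from −0.20 in cultures to 0.04 in tumours (exact permutation p = 0.0844).

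The largest shift of a chromosome in cultures was on chromosome 18, where 149 genes had a mean shift of 0.87 toward BDEneu (exact permutation p = 0.00216), with 66 called higher and 1 lower. A copy number difference carried by the lines may be the source: the tumours of the same lines, which are other samples, shifted the same way by 0.32 (exact permutation p = 0.00866). That test is not particular to chromosome 18 or to copy number, since 17 of the 21 chromosomes passed it in tumours, the others with smaller shifts. BDEsp tumours 1 and 2, with title numbers 28 and 30, stood at 0.069 and 0.065, near the 0.121 to 0.184 of BDEneu tumours. The other BDEsp tumours stood at −0.382 to −0.126, so most of the tumour shift came from them and followed the title numbers. Slower growth of BDEneu cultures 3 and 5 is argued against, since the shift was 0.88 without them. Stable regulation of these genes without a change in copy number was not tested and stays open.

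Other splits of the samples tested whether chance could give as many called genes. For cultures the real split gave 1273 genes and the highest of the others 0, for tumours 893 and 402, for BDEneu tumours against cells 2681 and 2248, and for BDEsp tumours against cells 2388 and 1428, each with 1 of 100 splits, the real one, as large. For metastases the real split gave 416 and the highest other 3, with 1 of 56 splits as large. In each comparison no other split tried gave as many genes. The smallest share the splits can give is 1 of 100, or 1 of 56 for metastases, so chance is less likely but not excluded. The splits also take the samples as independent, which the labels do not state.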
